A study of Xenopus laevis with 28 samples.

How the data were processed

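The authors deposited TPM values per gene model, in 28 columns that sum to about 1e6 each, and these were used as given. Per the submitters' processing notes BWA 0.7.10 and RSEM 1.2.19 were used before deposition. The label of the deposited values names BWA-MEM, RSEM and the cDNA set JGIv18pV2. Settings are not given. No reads were processed again, and neither depth nor expression floors are known.

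Gene models were tested if TPM was at least 1 in at least 2 of the 22 libraries of the staged series (28196 models). A linear model of log2(TPM + 1) on stage with clutch as an additive block was fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend, 10 residual degrees of freedom). All tests were two-sided and adjusted by Benjamini and Hochberg within each contrast. Calls were made at an adjusted p under 0.05. The 6 contrasts were egg to stage 8, 8 to 9, 9 to 12, 12 to 20, 20 to 30 and 30 to 40, beside an F-test over the 11 stages and a test of the clutch term. The ratio of L to S copies was fitted in the same way in pairs with 1 copy of each suffix and a summed TPM of at least 2 in 2 libraries. Library medians of that ratio were compared by exact permutation of stages within clutch. Libraries were compared by Spearman correlation. Oocyte libraries have no replicate and were not tested.

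The 30 gene lists were written before the data were examined and tested with camera at a preset correlation of 0.01, with the 180 list tests adjusted together, and again with an estimated correlation. They are maternal localized and germ plasm, oocyte and egg maturation, early zygotic mesendoderm and organizer, pluripotency and neuroectoderm, neurons and synapse, neural crest, brain regionalisation, hox genes, myogenic regulators and skeletal muscle, heart, blood and globin, endothelium, epidermis and keratins, multiciliated cells, ionocytes and small secretory cells, cement gland and hatching gland, lens, retina and phototransduction, liver and plasma proteins, exocrine and endocrine pancreas, gut and endoderm, pronephros, notochord and cartilage matrix, cytosolic ribosomal proteins, nuclear genes of oxidative phosphorylation, cell cycle and DNA replication, histones and linker histones, maternal mRNA clearance and translation control, thyroid and tadpole hormone axis, and immune.

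Rules for naming genes were also set before the data were examined. Per contrast these are the 10 largest rises and falls among called genes with a symbol, the same direction in both clutches and a mean TPM of at least 10 in the higher stage, with 1 model per symbol. From egg to stage 8, 2634 and 67 symbols met the rule, from 8 to 9 33 and 0, from 9 to 12 609 and 2787, from 12 to 20 564 and 677, from 20 to 30 53 and 48, and from 30 to 40 48 and 325. List members were the 4 called with the largest change. Clutch genes needed a mean TPM of at least 10 and the same direction in 10 of 11 stages, homeolog pairs a summed mean TPM of at least 20, and oocyte genes a TPM of at least 50. Genes named from fits without the library labelled stage 40 Ueno were chosen by the same rule after seeing the data.

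Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at TPM of at least 5, median-of-ratios scaling, quantile normalization, no replicate block, eBayes without trend, the second Ueno series added, and each library left out (in a contrast, those of its 2 stages). Chosen after seeing the data were fits without a library of another stage (the library labelled stage 40 Ueno in 5 contrasts), and without that library with other scalings in all 6. So were fits without both late Ueno libraries, list tests with libraries left out or scaled, and 3 filters for the homeolog medians. Refseq symbols could not be joined, since 0 model numbers matched.

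The methods were tested on simulated data with 100 changed genes at each size of change. From stage 20 to stage 30, 0 were called at a log2 change of 1 and 49 at 3, with 3 false calls among 25875 genes. With the spread of the fit without the library labelled stage 40 Ueno, these were 7 and 91 (3 false). The clutch term called 40 and 99 (9 false), and the homeolog fit 96 and 100 (8 false). To check the pairing by clutch, the differences between the clutches at 2 stages were correlated across genes. The median was 0.387 over 55 stage pairs (-0.204 to 0.877), and all 45 pairs without stage 40 were over 0.1.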

Results

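The series measured polyA RNA of *Xenopus laevis* (J strain) from oocytes to tadpoles in 28 libraries. Eggs and 10 stages of Nieuwkoop and Faber, from stage 8 (blastula) to stage 40 (tadpole), were sampled in 2 clutches named Taira and Ueno, with 1 library per clutch and stage (n = 2 per stage). The Ueno set also held 3 oocyte libraries (classes 1-2, 3-4 and 5-6) and 3 libraries of a second series (stages 8, 10 and 35), none replicated. The deposited values were TPM for 25308 named and 20523 unnamed gene models, of which 13451 carry the suffix L and 9742 the suffix S for the long and short subgenomes. TPM keeps no read counts. Here ± after a log2 fold is the standard error of the limma fit, and ± after a TPM value is the SD (n = 2). Folds are differences of log2(TPM + 1), which understates changes of genes with low TPM.

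Among the 11 Ueno libraries of the staged series, without oocytes and the second series, the closest to a Taira library by rank correlation was that of the same stage in 7 of 11 cases. The exceptions were stage 8 (closest to stage 9), stage 20 (closest to stage 15), and stages 35 and 40 (both closest to stage 30). The stage 35 library of the second series was closer to these, at 0.962 with stage 35 Taira and 0.948 with stage 40 Taira. Correlations between the clutches at the same stage ran from 0.892 at stage 35 to 0.971 at stage 9, apart from stage 40. The library labelled stage 40 Ueno had a Spearman correlation of 0.488 with stage 40 Taira but 0.964 with egg Ueno and 0.938 with egg Taira. Muscle actin actc1.L (Xelaev18039999m) was 158 TPM in stage 40 Taira and 0.120 in the library labelled stage 40 Ueno. The neural gene sox2.S (Xelaev18002672m) was 31.4 and 0.390. The maternal transcript myod1.L (Xelaev18021662m) went the other way, at 33.0 in stage 40 Taira, 253 in the labelled library and 186 in egg Ueno. Of 366 genes with at least 50 TPM in stage 40 Taira and under 1 in both eggs, the median in the labelled library was 0% of the Taira level, against 67.0% in stage 35 Ueno. Contrasts were therefore also fitted without this library, an alternative chosen after seeing the data except from stage 30 to stage 40, where each library was to be left out in turn.

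**Figure D1:**
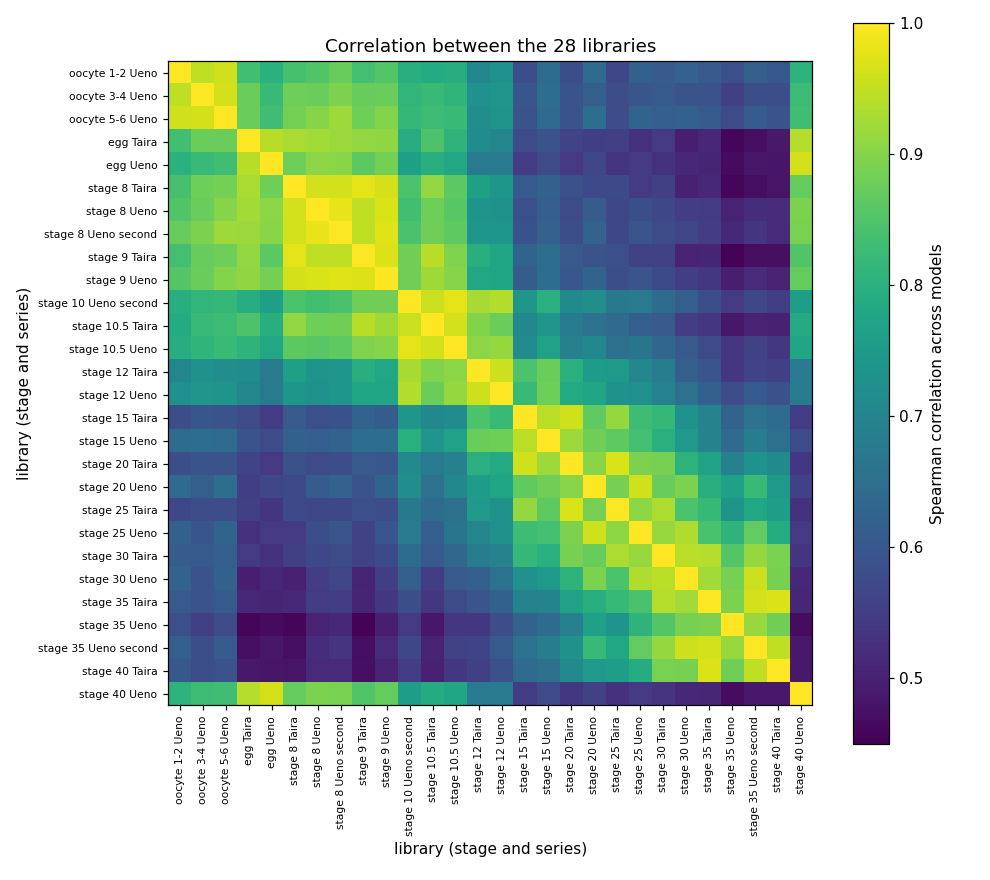
Spearman correlation (color scale) of log2(TPM + 1) between all 28 libraries, named on both axes by stage and clutch. The library labelled stage 40 Ueno reaches 0.964 with egg Ueno and 0.488 with stage 40 Taira.

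Known stage markers were read as landmarks. The organizer gene gsc.L (Xelaev18039577m) was at 4.28 and 3.03 TPM (Taira and Ueno) at stage 9, 66.3 and 53.9 at stage 10.5 and 11.9 and 12.49 at stage 12. The mesoderm T-box gene t.L (Xelaev18026860m) was at 3.31 and 3.08 at stage 9, 335 and 486 at stage 12 and 57.2 and 113 at stage 15. The neural gene sox2.S was at 4.28 and 1.35 at stage 8, 28.2 and 30.4 at stage 9 and 112 and 150.2 at stage 25. The muscle regulator myod1.S (Xelaev18024659m) was at 2.83 and 1.18 at stage 9 and 440.1 and 703 at stage 15, while its homeolog myod1.L was already at 53.5 and 186 in the egg and 26.6 and 15.3 at stage 8. Muscle actin actc1.L was at 0.240 and 0.740 at stage 12 and 29.8 and 42.3 at stage 15. The globin hba-l5.Sp (Xelaev18900566) was at 12.24 and 4.91 at stage 30 and 79.1 and 101 at stage 35. The organizer factor nodal3.L3 (Xelaev18018867m) was at 9.07 and 3.81 at stage 9 and 12.0 and 1.66 at stage 10.5, and sia1.S (Suzuki00018) at 3.70 and 0.490 at stage 9. The files hold no model named vegt, alb or rho.

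**Figure D2:**
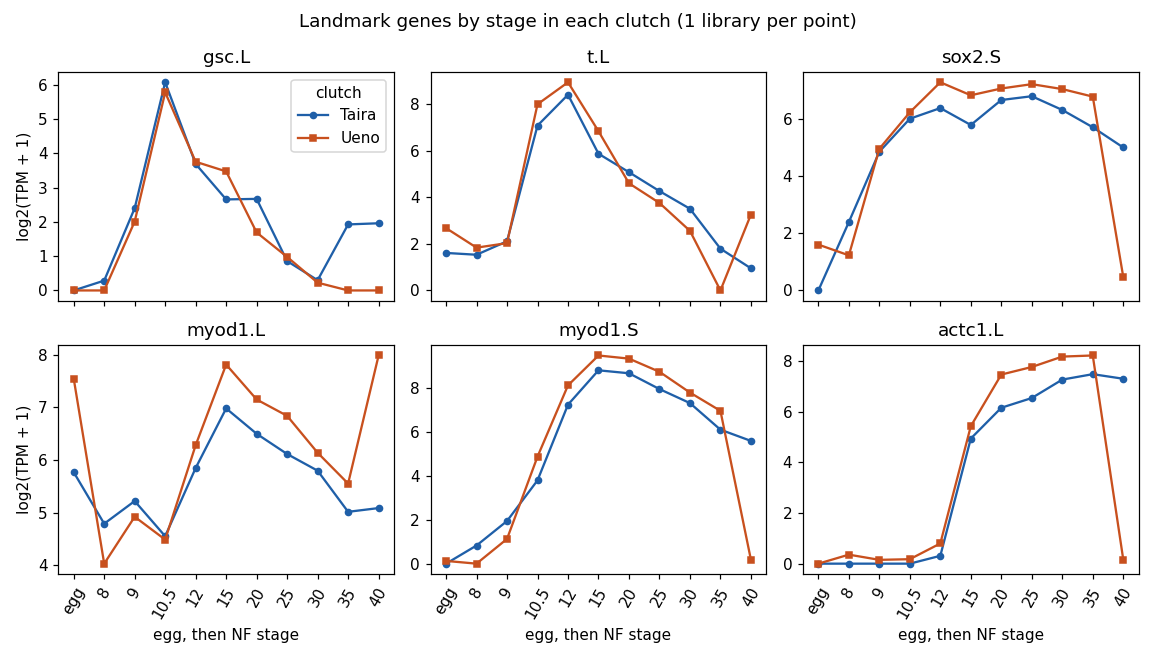
log2(TPM + 1) by stage for gsc.L, t.L, sox2.S, myod1.L, myod1.S and actc1.L, with 1 library per point and a line per clutch (Taira circles, Ueno squares). The last Ueno point, the library labelled stage 40 Ueno, is at 0.120 TPM of actc1.L where Taira has 158.

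Across all 11 stages, 23271 of 28196 tested gene models differed among stages (limma F-test, any stage: genes that differ among the 11 stages). From egg to stage 8, the interval of fertilization and cleavage, most called genes were higher at stage 8. The replication licensing factor cdt1.S (Xelaev18024859m, 5.2 ± 0.59, from 4.73 ± 1.88 to 209 ± 63.5 TPM) rose most. The Nodal pathway repressor tgif1.L (Xelaev18031876m, 5.14 ± 0.61), the kinase nuak2.L (Xelaev18012230m, 5.11 ± 0.47), the p53-binding tp53bp2.L (Xelaev18026271m, 5.05 ± 0.66) and the Cdk5 activator cdk5r2.S (Xelaev18047038m, 4.71 ± 0.54) rose with it. So did the Notch modifier lfng.S (Xelaev18047541m, 4.66 ± 0.61), pwp1-like.S (Xelaev18019894m, 4.58 ± 0.94), the ubiquitin ligase peli2.S (Xelaev18028489m, 4.47 ± 0.49), the nucleolar helicase ddx56.L (Xelaev18018637m, 4.47 ± 0.60) and the palmitoyltransferase zdhhc13.L (Xelaev18021740m, 4.44 ± 0.88). Among the genes that fell were the mitotic kinase aurka.L (Xelaev18043488m, -3.57 ± 1.00, from 1183 ± 803 to 86.5 ± 6.99 TPM), the kinase pbk.L (Xelaev18028391m, -3.84 ± 0.74), the mitotic entry factor cdca3-like.L (Xelaev18034430m, -2.83 ± 0.80) and the centrosomal ubiquitin ligase trim37.S (Xelaev18015341m, -3.92 ± 1.06). Also lower were arl6ip1.L (Xelaev18045200m, -3.61 ± 0.52), rfwd3.L (Xelaev18022810m, -3.14 ± 0.92), the spermine oxidase smox.L (Xelaev18004815m, -3.01 ± 1.02), the stress gene gadd45a.S (Xelaev18025104m, -2.82 ± 0.65), znhit1.1 (Xelaev18001010m, -2.81 ± 0.43) and the nucleoporin ndc1.L (Xelaev18023197m, -2.80 ± 0.76). The maternal muscle regulator myod1.L (-2.25 ± 0.66) fell (adjusted p = 0.023). Adjusted p ran from 9.41e-05 to 0.00276 in the 10 genes named as higher and 0.000359 to 0.0443 in the 10 named as lower.

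Of the oocyte and egg maturation genes (5 higher, 24 not called; 4 higher adjusted over the list alone), patl2.L (Xelaev18011481m, 3.42 ± 0.87), gdf9.L (Xelaev18017189m, 3.13 ± 0.70) and zar1.S (Xelaev18009039m, 2.37 ± 0.71) were higher (camera adjusted p = 0.401), but 0 higher and 0 lower were called after median-of-ratios scaling. Of the germ plasm and localized genes (4 higher, 16 not called; 6 higher adjusted over the list alone), the germ cell helicase ddx4.L (Xelaev18008273m, 2.92 ± 0.62) and otx1.L (Xelaev18026512m, 3.98 ± 0.40) were higher (camera adjusted p = 0.649; 1 higher and 2 lower after that scaling). Genes of mRNA clearance and translation control (14 higher, 32 not called; 15 higher adjusted over the list alone) included the uridyltransferases zcchc6.L (Xelaev18006944m, 3.57 ± 0.52) and zcchc11.L (Xelaev18023180m, 3.29 ± 0.39) and the decay factor zfp36l1.L (Xelaev18040107m, 3.24 ± 0.61) (camera adjusted p = 0.633; 5 higher and 5 lower after that scaling). Cell cycle genes (16 higher, 6 lower, 52 not called; 16 higher and 7 lower adjusted over the list alone) included cdc25c.S (Xelaev18021335m, 3.70 ± 0.61) and mcm2.L (Xelaev18023987m, 3.40 ± 0.98), yet lay below the other genes as a group (camera adjusted p = 0.00726 and 0.849 with an estimated correlation, median -0.04, mean 0.11; 5 higher and 13 lower after that scaling). Ribosomal proteins (0 of 54 called, also adjusted over the list alone) lay below the other genes (median -0.52, camera adjusted p = 7.02e-08 and 0.849 with an estimated correlation). So did oxidative phosphorylation genes (2 higher, 3 lower, 83 not called; 0 called adjusted over the list alone), with ndufa1.S (Xelaev18042220m, -2.20 ± 0.60) lower and ndufs5.L (Xelaev18012619m, 2.08 ± 0.59) higher (median 0.00, mean 0.09, camera adjusted p = 0.000136 and 0.849 with an estimated correlation; 0 higher and 17 lower after that scaling). Of the members named, patl2.L (0.121; 0.0027 to 0.121), gdf9.L (0.146; 6.31e-06 to 0.146), zar1.S (0.424; 0.00185 to 0.424), ddx4.L (0.0793; 0.00113 to 0.0793), mcm2.L (0.171; 0.00198 to 0.171) and ndufs5.L (0.42; 0.00034 to 0.42) had an adjusted p over 0.05 after median-of-ratios scaling, given before the range over both scalings and the fits without the library labelled stage 40 Ueno. Over all contrasts 89 of 180 list tests were called, and in 8 of these the median had the other sign than the test.

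limma called 6589 models higher and 150 lower (97.8% of the called higher), and 6433 and 145 of these changed over 2-fold. Median-of-ratios scaling gave 1457 and 1436 (50.4% higher) and quantile normalization 1286 and 549 (70.1%), so the direction of the excess depends on the scaling. The median of all genes was 0.30 in TPM and 0.00 after median-of-ratios scaling. All 20 named genes kept their call and direction under that scaling. Leaving out egg Taira, egg Ueno, stage 8 Taira and stage 8 Ueno in turn gave 5137 and 90, 3477 and 44, 4882 and 49, 3137 and 37 higher and lower. Of the named genes, 5, 7, 6 and 6 were then not called. The counts were 9250 and 1045 without the library labelled stage 40 Ueno and 9259 and 1058 without stage 40 Taira.

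From stage 8 to stage 9, across the midblastula transition, all called genes rose. The ectodermal forkhead gene foxi4.2.L (Xelaev18004992m, 5.54 ± 0.59, from 1.47 ± 1.71 to 101 ± 24.6 TPM) rose most, followed by the forkhead gene foxh1.2.L (Xelaev18032544m, 5.25 ± 0.65), the cell cycle phosphatase cdc25b.L (Xelaev18004874m, 5.18 ± 0.93) and the early zygotic gs17.L (Xelaev18043173m, 4.95 ± 0.61). Others were the histidine ammonia lyase hal.1.L (Xelaev18017500m, 4.24 ± 0.51), the retinoic acid hydroxylase cyp26a1.S (Xelaev18036884m, 4.24 ± 0.76), the pluripotency gene pou5f3.2.S (Xelaev18041474m, 4.2 ± 0.51, from 5.89 ± 3.75 to 119 ± 36.7 TPM) and the Wnt target sp5l.L (Xelaev18013447m, 4.11 ± 0.56). The lysophosphatidic acid receptor lpar6.L (Xelaev18013285m, 3.90 ± 0.52) and the Hes family gene hes7-2_L (Xelaev18019217m, 3.87 ± 0.76) followed. Neuroectoderm genes zic1.S (Xelaev18029829m, 3.67 ± 0.55), foxd4l1.1.L (Xelaev18006860m, 3.60 ± 0.48) and irx1.S (Xelaev18033303m, 3.53 ± 0.55), the proneural genes neurog3.S (Xelaev18037155m, 2.91 ± 0.49) and neurog3.L (Xelaev18034898m, 2.65 ± 0.46), and the notochord genes not.S (Xelaev18008736m, 3.39 ± 0.59) and foxa4.L (Xelaev18022299m, 3.01 ± 0.51) also rose. Adjusted p ran from 0.000712 to 0.0316 in the 10 genes named by the rule. Median-of-ratios scaling ended the call of cdc25b.L (adjusted p = 0.304; all alternatives 3.24e-06 to 0.304), cyp26a1.S (0.125; 0.000508 to 0.433) and hes7-2_L (0.113; 0.00626 to 0.677).

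Early zygotic mesendoderm and organizer genes (25 higher, 51 not called; 47 higher adjusted over the list alone) had a median of 1.58 (camera adjusted p = 1.05e-136 and 0.00044 with an estimated correlation). Pluripotency and neuroectoderm genes (10 higher, 14 not called; 16 higher adjusted over the list alone) had a median of 1.89 (camera adjusted p = 8.81e-62 and 0.00044). These were the only 2 of the 180 list tests called with an estimated correlation. Of the brain regionalisation genes (3 higher, 35 not called; 4 higher adjusted over the list alone), lhx5.L (Xelaev18007446m, 3.09 ± 0.48), lhx5.S (Xelaev18010382m, 2.67 ± 0.38) and fgf8.L (Xelaev18034665m, 2.61 ± 0.47) rose (camera adjusted p = 2.79e-07 and 0.849). Neural crest genes (0 of 26 called; 1 higher adjusted over the list alone) lay above the other genes (camera adjusted p = 0.000166 and 0.849). Of the immune genes (1 higher, 19 not called; 2 higher adjusted over the list alone), the chemokine receptor cxcr4.S (Xelaev18047057m, 2.64 ± 0.44) rose (camera adjusted p = 0.00269 and 0.849). Ionocyte genes (0 of 13 called, also adjusted over the list alone) lay above the other genes (camera adjusted p = 0.0272, 0.849 with an estimated correlation and 0.133 after median-of-ratios scaling, with alternatives from 0.00571 to 0.849). Lens genes (0 of 13 called, also adjusted over the list alone) lay below (median -0.48, camera adjusted p = 4.6e-06 and 0.849). Of the members named, zic1.S (0.0877; 0.000356 to 0.182), irx1.S (0.0796; 0.000434 to 0.0796), neurog3.S (0.4; 0.000434 to 0.704), neurog3.L (0.233; 0.00445 to 0.325), not.S (0.0778; 0.00295 to 0.0812), lhx5.S (0.271; 0.000508 to 0.271) and fgf8.L (0.292; 0.00674 to 0.324) had an adjusted p over 0.05 after median-of-ratios scaling.

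limma called 177 models higher and 0 lower, with 734 higher and 36 lower at an unadjusted p under 0.05. Lower calls were 1 with a pseudocount of 5, 4 without a filter on low values, 1 with quantile normalization and 0 with median-of-ratios scaling (77 higher). Leaving out stage 8 Taira, stage 8 Ueno, stage 9 Taira and stage 9 Ueno in turn gave 134 and 7, 54 and 2, 69 and 0, 96 and 2 higher and lower. Of the named genes, 1, 3, 3 and 3 were then not called. Leaving out any 1 library of stages 10.5, 12 or 15 gave 1 lower call, and leaving out the library labelled stage 40 Ueno or stage 40 Taira gave 319 and 1 and 316 and 1.

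From stage 9 to stage 12, across gastrulation, the connexin gjb1.L (Xelaev18038658m, 8.37 ± 1.2, from 0.455 ± 0.00707 to 481 ± 50.6 TPM), the keratins krt.L (Xelaev18043105m, 8.25 ± 0.62) and krt12.S (Xelaev18045889m, 7.85 ± 1.59), and trim29.L (Xelaev18035380m, 7.84 ± 1.02) rose. The caudal gene cdx1.S (Xelaev18020055m, 8.16 ± 0.63) and the secreted head inducer cer1.S (Xelaev18010056m, 7.99 ± 0.48, from 1.49 ± 0.955 to 607 ± 62.3 TPM) rose. So did the creatine synthesis gene gatm.L (Xelaev18018259m, 8.28 ± 1.15), the protease inhibitor a2m.S (Xelaev18036689m, 8.17 ± 1.2) and the neurotrophin receptor ngfr.S (Xelaev18032746m, 7.94 ± 0.98). The hydroxyacid oxidase hao1.L (Xelaev18026066m) was listed at 0 in both stage 9 libraries and at 247 ± 50.9 TPM at stage 12 (adjusted p = 9.96e-06). The cyclin ccnb5.L (Xelaev18018161m, -8.63 ± 2.07, from 887 ± 103 to 1.26 ± 0.559 TPM) and the meiotic arrest factor fbxo43-like.S (Xelaev18033879m, -7.53 ± 1.76) fell. So did the polyadenylation factor cpeb1.L (Xelaev18018089m, -6.76 ± 1.55), the decay factor zfp36l2.1.L (Xelaev18022134m, -7.12 ± 2.05) and the deadenylation adaptor btg4.L (Xelaev18035485m, -6.62 ± 1.93). The maternal ectoderm factor foxi2.S (Xelaev18036872m, -6.94 ± 1.36), the Nodal antagonist dand5.L (Xelaev18019052m, -6.33 ± 1.76), cdca7-like.1.L (Xelaev18013589m, -7.33 ± 2.08), rpain.S (Xelaev18015437m, -6.54 ± 1.58) and tmem171.L (Xelaev18008145m, -6.23 ± 1.51) were also lower. The range of adjusted p was 7.21e-07 to 0.00181 in the 10 genes named as higher and 0.00148 to 0.016 in the 10 named as lower. Median-of-ratios scaling ended the calls of cdca7-like.1.L (adjusted p = 0.0585; all alternatives 9.01e-07 to 0.118), zfp36l2.1.L (0.0641; 1.26e-07 to 0.0974), btg4.L (0.0697; 1.51e-06 to 0.0956) and dand5.L (0.0611; 1.79e-07 to 0.101).

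Of the early zygotic genes (51 higher, 6 lower, 19 not called; 55 higher and 7 lower adjusted over the list alone), the mesoderm genes t.L (6.59 ± 0.74) and t.S (Xelaev18029080m, 6.29 ± 0.50) rose (median 2.42, camera adjusted p = 3.78e-25 and 0.135 with an estimated correlation). Within the pluripotency list (13 higher, 2 lower, 9 not called; 14 higher and 2 lower adjusted over the list alone), pou5f3.1.L (Xelaev18038233m, 6.45 ± 0.49) rose while the maternal pou5f3.3.S (Xelaev18041473m, -6.13 ± 1.71) fell (camera adjusted p = 2.54e-08 and 0.21). Of the epidermis and keratin genes (17 higher, 9 not called, also adjusted over the list alone), the keratin krt5.7.S (Xelaev18016082m, 7.26 ± 1.97, from 8.99 ± 4.07 to 1469 ± 65.2 TPM) rose (median 2.95, camera adjusted p = 1.5e-12 and 0.378). Gut and endoderm genes (23 higher, 16 not called, also adjusted over the list alone) included cdx4.L (Xelaev18038743m, 6.84 ± 0.75) and cdx2.L (Xelaev18013752m, 6.79 ± 0.78) (median 2.97, camera adjusted p = 2.68e-14 and 0.633). Hox genes (17 higher, 1 lower, 54 not called, also adjusted over the list alone) included hoxd1.S (Xelaev18047201m, 6.51 ± 0.56) (camera adjusted p = 1.4e-08 and 0.849). Pronephros genes (12 higher, 2 lower, 20 not called, also adjusted over the list alone) included osr2.S (Xelaev18033888m, 5.04 ± 0.65) (camera adjusted p = 3.85e-05 and 0.849). Neural crest genes (10 higher, 1 lower, 15 not called, also adjusted over the list alone) included msx1.L (Xelaev18005111m, 6.76 ± 1.02) (camera adjusted p = 6.56e-05 and 0.849). Of the muscle genes (4 higher, 4 lower, 30 not called; 4 higher and 2 lower adjusted over the list alone), myod1.S (6.13 ± 1.16) and pygm.S (Xelaev18028883m, 6.83 ± 1.04) rose, and myf5.L (Xelaev18017433m) went from a listed 0 to 70.9 ± 5.38 TPM. That list had a camera adjusted p = 0.0143 (0.849 with an estimated correlation and 0.429 after median-of-ratios scaling, alternatives from 0.000987 to 0.849). Retina genes (5 higher, 24 not called; 4 higher adjusted over the list alone) included rpe65.S (Xelaev18025098m, 6.29 ± 0.69) (camera adjusted p = 0.000778 and 0.849). Heart genes (3 higher, 20 not called; 2 higher adjusted over the list alone) included gata5.L (Xelaev18043514m, 3.03 ± 0.52) (camera adjusted p = 0.00335, 0.849 with an estimated correlation and 0.133 after median-of-ratios scaling, with alternatives from 0.000999 to 0.849). Liver genes (2 higher, 32 not called, also adjusted over the list alone) had a camera adjusted p = 0.0132 (0.561 after that scaling and 0.87 with an estimated correlation, alternatives from 0.00421 to 0.87).

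Oocyte and egg maturation genes (15 lower, 14 not called; 20 lower adjusted over the list alone) had a median of -3.10 (camera adjusted p = 0.00263 and 0.849 with an estimated correlation). Of the germ plasm genes (11 lower, 9 not called; 12 lower adjusted over the list alone), dnd1.L (Xelaev18017004m, -5.19 ± 1.23), velo1.L (Xelaev18031248m, -3.99 ± 0.99) and vg1.L (Suzuki00050_vg1.2, -3.73 ± 1.03) fell (camera adjusted p = 0.0471, 0.849 with an estimated correlation and 0.0989 after median-of-ratios scaling, with alternatives from 0.0031 to 0.849). Ribosomal protein genes (14 higher, 40 not called; 0 called adjusted over the list alone) lay above the other genes (median 1.70, camera adjusted p = 6.46e-12 and 0.849 with an estimated correlation). The histone variant h2afz.L (Xelaev18005732m, 2.24 ± 0.39, from 754 ± 3.61 to 3575 ± 106 TPM) rose. Of the cell cycle genes (6 higher, 18 lower, 50 not called, also adjusted over the list alone), the cyclin ccna1.L (Xelaev18013704m, -6.20 ± 2.07) and the checkpoint kinase chek1.S (Xelaev18037351m, -4.01 ± 0.79) fell. The list was not called (camera adjusted p = 0.535). Nor were the genes of mRNA clearance and translation control (5 higher, 18 lower, 23 not called; 6 higher and 20 lower adjusted over the list alone; camera adjusted p = 0.42). Of the members named, pou5f3.3.S (0.0655; 6.95e-07 to 0.0655), velo1.L (0.065; 4.57e-06 to 0.065), vg1.L (0.102; 1.43e-05 to 0.102) and ccna1.L (0.106; 8.89e-07 to 0.106) had an adjusted p over 0.05 after median-of-ratios scaling.

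limma called 2556 models higher and 7280 lower (26.0% higher). Median-of-ratios scaling turned this excess to 3801 and 2680 (58.6% higher) and quantile normalization gave 3485 and 3457 (50.2%). The median of all genes was -0.34 in TPM and 0.05 after median-of-ratios scaling. Leaving out stage 9 Taira, stage 9 Ueno, stage 12 Taira and stage 12 Ueno in turn gave 1570 and 5342, 1849 and 4071, 1906 and 4571, 1660 and 4824 higher and lower. Of the named genes, 4, 4, 2 and 5 were then not called. The counts were 3725 and 10014 without the library labelled stage 40 Ueno and 3724 and 10037 without stage 40 Taira.

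From stage 12 to stage 20, across neurulation, the fast myosin light chain mylpf.L (Xelaev18045645m, 9.10 ± 2.30, from 1.25 ± 1.44 to 1167 ± 560.1 TPM) rose most. The actin act3.L (Xelaev18022225m, 7.63 ± 1.77), desmin des.1.S (Xelaev18047019m, 7.52 ± 1.40), troponin C tnnc2.S (Xelaev18046533m, 7.43 ± 1.96) and the myosin heavy chain myh8-like.L (Xelaev18039829m, 7.13 ± 1.27) rose with it. So did sarcalumenin srl-like.L (Xelaev18045450m, 6.89 ± 1.25), the calcium channel subunit cacng1.L (Xelaev18044257m, 6.59 ± 1.01), the F-box gene fbxl22-like.S (Xelaev18020807m, 6.57 ± 0.75), klhl41.L (Xelaev18044662m, 6.54 ± 0.97) and the orphan nuclear receptor nr2f5.S (Xelaev18042745m, 6.41 ± 0.84). Muscle actin actc1.L (6.26 ± 1.45) was called as well. The head inducer cer1.S (-7.74 ± 0.48, from 607 ± 62.3 to 2.19 ± 2.07 TPM), the pluripotency gene pou5f3.2.L (Xelaev18038231m, -7.38 ± 0.61), the Nodal coreceptor tdgf1.3.L (Xelaev18006973m, -7.37 ± 0.87) and the homeobox gene crx.L (Xelaev18039352m, -6.35 ± 0.87) fell. The endoderm factor mixer.L (Xelaev18026298m, -6.18 ± 0.46), pnhd.S (Xelaev18009897m, -5.84 ± 0.42), the organizer ligand admp.S (Xelaev18009898m, -5.29 ± 0.44) and the T-box gene eomes.S (Xelaev18033132m, -5.16 ± 0.56) fell as well. So did the cysteine dioxygenase cdo1.S (Xelaev18010763m, -5.45 ± 0.88) and the receptor il5ra.L (Xelaev18023902m, -5.32 ± 1.36). Limma gave adjusted p from 0.000199 to 0.0208 in the 10 named as higher and 1.31e-06 to 0.0185 in the 10 named as lower. All 20 kept their call under median-of-ratios scaling.

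Hox genes (41 higher, 2 lower, 29 not called; 57 higher and 2 lower adjusted over the list alone) had the most higher members of any list in this contrast (median 1.55, camera adjusted p = 1.16e-20 and 0.633 with an estimated correlation), led by hoxb6.L (Xelaev18043228m, 5.18 ± 0.56), hoxb9.S (Xelaev18045992m, 4.84 ± 0.53) and hoxb7.L (Xelaev18043229m, 4.78 ± 0.52). Skeletal muscle genes (13 higher, 25 not called; 16 higher adjusted over the list alone) had a camera adjusted p = 9.33e-06 and 0.849 with an estimated correlation. Of the brain regionalisation genes (16 higher, 4 lower, 18 not called; 19 higher and 4 lower adjusted over the list alone), the hindbrain genes mafb.L (Xelaev18043909m, 4.1 ± 0.81) and egr2.L (Xelaev18034483m, 4.02 ± 0.38) rose and lhx5.L (-3.69 ± 0.48) fell (camera adjusted p = 4.03e-05 and 0.849). Neuronal genes (9 higher, 28 not called; 12 higher adjusted over the list alone) included the tubulin tubb2b.S (Xelaev18033421m, 4.52 ± 1.38) and isl1.S (Xelaev18010976m, 2.97 ± 0.57) (camera adjusted p = 0.00101 and 0.849). Of the neural crest genes (6 higher, 20 not called, also adjusted over the list alone), sox10.L (Xelaev18023692m, 3.72 ± 0.84) and sox8.S (Xelaev18047768m, 3.55 ± 0.61) rose (camera adjusted p = 0.0679). Blood genes (8 higher, 16 not called, also adjusted over the list alone) included the carbonic anhydrase ca2.L (Xelaev18032156m, 6.40 ± 1.41) and the myeloid factor spib.L (Xelaev18036193m, 4.49 ± 0.67) (camera adjusted p = 0.00475 and 0.849). Cement and hatching gland genes (3 higher, 3 not called; 5 higher adjusted over the list alone) included agr2.L (Xelaev18030964m, 4.83 ± 1.17) and pitx1.L (Xelaev18016963m, 3.76 ± 0.91) (camera adjusted p = 0.00316 and 0.849). Ionocyte genes (5 higher, 8 not called, also adjusted over the list alone) included dmrt2.L (Xelaev18006848m, 3.22 ± 0.51) (camera adjusted p = 0.0252 and 0.849). Multiciliated cell genes (7 higher, 1 lower, 31 not called; 8 higher and 1 lower adjusted over the list alone) included spag6.L (Xelaev18030785m, 3.99 ± 0.88) and tekt3.S (Xelaev18046805m, 3.82 ± 0.74) (camera adjusted p = 0.0316 and 0.849). Of the pronephros genes (4 higher, 2 lower, 28 not called; 5 higher and 2 lower adjusted over the list alone), pax8.L (Xelaev18018610m, 3.80 ± 0.40) and slc12a1.L (Xelaev18018227m, 4.07 ± 0.79) rose and lhx1.S (Xelaev18015014m, -2.97 ± 0.38) fell (camera adjusted p = 0.223). Of the notochord and cartilage genes (8 higher, 5 lower, 24 not called; 12 higher and 6 lower adjusted over the list alone), the collagen col9a3.S (Xelaev18046297m, 4.50 ± 1.12) rose and t.S (-4.49 ± 0.50) fell (camera adjusted p = 0.181). Of the epidermis genes (6 higher, 2 lower, 18 not called; 9 higher and 3 lower adjusted over the list alone), the stem cell factor tp63.L (Xelaev18027483m, 3.35 ± 0.55) rose. This list had a camera adjusted p = 0.0411 (0.849 with an estimated correlation and 0.0692 after median-of-ratios scaling, alternatives from 0.000416 to 0.849).

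Early zygotic genes (48 lower, 28 not called; 1 higher and 53 lower adjusted over the list alone) lay below the other genes (camera adjusted p = 2.45e-26 and 0.135 with an estimated correlation). So did pluripotency genes (15 lower, 9 not called; 16 lower adjusted over the list alone; camera adjusted p = 2.5e-12 and 0.114). Of the cell cycle genes (8 lower, 66 not called, also adjusted over the list alone), geminin gmnn.S (Xelaev18033520m, -4.13 ± 1.2), cdt1.S (-2.85 ± 0.59) and ccne2.L (Xelaev18032248m, -2.83 ± 0.53) fell (camera adjusted p = 0.0036 and 0.849 with an estimated correlation). Ribosomal (1 higher, 53 not called; 0 called adjusted over the list alone) and oxidative phosphorylation genes (4 higher, 84 not called; 1 higher adjusted over the list alone) lay above the other genes (camera adjusted p = 4.75e-07 and 0.0184, and 0.849 and 0.889 with an estimated correlation). Of the members named, tubb2b.S (0.0567; 2.07e-07 to 0.0567) had an adjusted p over 0.05 after median-of-ratios scaling.

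limma called 2359 models higher and 2141 lower (52.4% higher). Leaving out stage 12 Taira, stage 12 Ueno, stage 20 Taira and stage 20 Ueno in turn gave 607 and 748, 937 and 614, 1037 and 1262, 1023 and 518 higher and lower. Of the named genes, 4, 4, 3 and 4 were then not called. The counts were 5277 and 5086 without the library labelled stage 40 Ueno and 5289 and 5103 without stage 40 Taira.

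From stage 20 to stage 30, the interval of tailbud formation, the keratin krt16.L (Xelaev18043117m, 6.23 ± 1.14, from 1.93 ± 1.26 to 211 ± 42.3 TPM) had the largest fold. The muscle phosphatase dupd1.1 (Xelaev18000570m, 4.78 ± 1.02), the glucose-6-phosphatase g6pc-like.1.S (Xelaev18046507m, 4.76 ± 0.97), the muscle phosphoglycerate mutase pgam2.S (Xelaev18020273m, 4.75 ± 1.03) and elastin eln2.L (Xelaev18045677m, 4.65 ± 0.92) rose. So did tmem82.L (Xelaev18036383m, 4.45 ± 0.77), xa-1-like.S (Xelaev18037722m, 4.45 ± 1.02) and the mitochondrial carrier slc25a12.L (Xelaev18044692m, 4.32 ± 0.85). The glucose-6-phosphatase g6pc2.L (Xelaev18043834m) and tmem82.1 (Xelaev18000059m) went from a listed 0 to 38.9 ± 30.4 and 21.8 ± 14.6 TPM. The aminopeptidase anpep.S (Xelaev18020528m, -5.25 ± 0.61, from 70.2 ± 59.5 to 0.515 ± 0.191 TPM), angpt4.S (Xelaev18021230m, -4.81 ± 0.46), gs17.L (-4.71 ± 0.61) and the endoderm factor sox17b.1.L (Xelaev18032021m, -4.2 ± 0.50) fell. So did pou5f3.1.L (-4.09 ± 0.49), the zinc transporter slc30a8.L (Xelaev18032308m, -3.96 ± 0.47), ficd.S (Xelaev18010387m, -3.84 ± 0.62), post.L (Xelaev18045807m, -3.77 ± 0.72), post.1 (Xelaev18003844m, -3.75 ± 0.68) and the ventral homeobox gene ventx3.2.S (Xelaev18036898m, -3.67 ± 0.51). Limma gave adjusted p from 0.00484 to 0.0498 in the 10 named as higher and 0.000326 to 0.0196 in the 10 named as lower. Median-of-ratios scaling ended the calls of pgam2.S (adjusted p = 0.0574; all alternatives 3.93e-08 to 0.347) and xa-1-like.S (0.0648; 6.87e-07 to 0.366).

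The globin hbd.S (Xelaev18047451m, 5.64 ± 0.64), the glial fatty acid binder fabp7.L (Xelaev18027016m, 4.68 ± 0.76), ifitm1.S (Xelaev18024344m, 4.67 ± 0.28) and the muscle gene myoz1.S (Xelaev18037139m, 4.65 ± 0.46) were called without the library labelled stage 40 Ueno but not with all 22 libraries. The same holds for the pigment genes dct.L (Xelaev18013152m, 4.63 ± 0.58) and tyr.S (Xelaev18016340m, 3.85 ± 0.36), the crystallin cryba1.S (Xelaev18014166m, 4.38 ± 0.44) and the apolipoproteins apoe.S (Xelaev18037761m, 4.51 ± 0.71) and apoa1.L (Xelaev18035462m, 4.31 ± 0.40). Adjusted p in these 9 was 2.48e-07 to 0.00116 without it and 0.058 to 0.44 with it. Oxidative phosphorylation (1 higher, 87 not called, also adjusted over the list alone) and neuronal genes (0 of 37 called, also adjusted over the list alone) lay above the other genes (medians 0.90 and 0.87, camera adjusted p = 2.68e-12 and 2.58e-05, 0.849 for each with an estimated correlation). So did muscle (2 higher, 36 not called, also adjusted over the list alone) and endothelium genes (2 higher, 18 not called; 3 higher adjusted over the list alone), the latter with egfl7.S (Xelaev18041539m, 2.95 ± 0.46) (camera adjusted p = 0.000373 and 0.000443, 0.849 for each with an estimated correlation). Lens, liver, heart and blood genes did too (camera adjusted p = 0.00475, 0.00669, 0.00759 and 0.00176, 0.849 each with an estimated correlation). All 22 libraries gave 0 calls, as for neurons (3 blood genes over the list alone), so rises stay possible. Early zygotic (16 lower, 60 not called; 2 higher and 32 lower adjusted over the list alone) and pluripotency genes (4 lower, 20 not called; 5 lower adjusted over the list alone) lay below (camera adjusted p = 5.01e-18 and 1.33e-05, and 0.26 and 0.446 with an estimated correlation). Brain (3 lower, 35 not called; 6 lower adjusted over the list alone) and hox genes (3 lower, 69 not called; 1 higher and 13 lower adjusted over the list alone) did too, with egr2.L (-2.44 ± 0.38) and hoxa7.S (Xelaev18033074m, -2.88 ± 0.45) (camera adjusted p = 0.00475 and 0.00185, 0.849 for each with an estimated correlation). 

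limma called 175 models higher and 216 lower (44.8% higher). The counts were 2025 and 1325 without the library labelled stage 40 Ueno, which this contrast does not use, and 2037 and 1350 without stage 40 Taira. Leaving out stage 20 Taira, stage 20 Ueno, stage 30 Taira and stage 30 Ueno in turn gave 6 and 25, 16 and 152, 6 and 38, 10 and 25 higher and lower. Of the named genes, 14, 9, 13 and 14 were then not called. Leaving out a stage 9 or stage 12 library of either clutch gave 110 or 116 higher.

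From stage 30 to stage 40, 1 of the 2 stage 40 libraries is the library labelled stage 40 Ueno, so directions below are drawn in part from it. With all 22 libraries the cysteine dioxygenase cdo1.S (4.36 ± 0.88), serinc2.L (Xelaev18012063m, 4.14 ± 0.81), the transaminase gpt2.S (Xelaev18034101m, 3.99 ± 0.88), the glycolytic mutase pgam1.S (Xelaev18036980m, 3.95 ± 0.69) and hebp2.L (Xelaev18026611m, 3.79 ± 0.81) rose. The glycogen regulator ppp1r3c.2.S (Xelaev18020178m, 3.75 ± 0.75), the phospholipid methyltransferase pemt.L (Xelaev18045570m, 3.72 ± 0.49), tprg1-like.L (Xelaev18027481m, 3.58 ± 0.53), rgs4.S (Xelaev18025450m, 3.45 ± 0.77) and the chemokine CXCL8e.S (Xelaev18009499m, 3.33 ± 0.49) rose as well. The larval keratin krt.L (-7.26 ± 0.62), adhfe1.S (Xelaev18033772m, -6.63 ± 0.76), the connexin gjb1.L (-5.62 ± 1.2), desmin des.1.L (Xelaev18044480m, -5.53 ± 1.16) and elastin eln2.L (-5.35 ± 0.92) fell. So did the gluconeogenic fbp1.L (Xelaev18006951m, -5.30 ± 1.32), the keratin krt16.S (Xelaev18045886m, -5.25 ± 1.13) and the muscle enzymes pygm.S (-5.10 ± 1.04), gamt.S (Xelaev18009762m, -5.08 ± 1.23) and pgam2.L (Xelaev18018627m, -5.08 ± 1.3). Adjusted p ran from 0.00197 to 0.0295 in the 10 named as higher and 0.00021 to 0.0444 in the 10 named as lower. Without the library labelled stage 40 Ueno the folds shrank, to -5.80 for krt.L, -2.46 for gjb1.L, 2.19 for cdo1.S and 3.05 for pemt.L. The calls of hebp2.L, rgs4.S, krt16.S and pgam2.L ended (adjusted p = 0.0973, 0.0926, 0.0538 and 0.175; all alternatives 9.67e-05 to 0.195, 5.38e-06 to 0.232, 8.23e-07 to 0.384 and 5.74e-07 to 0.559). Median-of-ratios scaling ended those of fbp1.L, gamt.S and pgam2.L (0.0721, 0.0671 and 0.0686; all alternatives 1.25e-08 to 0.262 and 1.62e-08 to 0.242 for the former pair).

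Without the library, stage 40 rests on Taira alone, and the genes named next are among the 942 that rose and the 491 that fell. Transthyretin ttr.L (Xelaev18031959m, 10.85 ± 0.75) went from 1.04 TPM at stage 30 to 4665 in stage 40 Taira, and its homeolog ttr.S (Xelaev18033680m, 9.64 ± 0.62) to 5489. The apolipoprotein apoa1.S (Xelaev18037384m, 7.20 ± 0.74), fibrinogen fgg.S (Xelaev18009208m, 6.80 ± 0.63), the fatty acid binding proteins fabp2.L (Xelaev18005684m, 8.11 ± 0.45), fabp1.L (Xelaev18004989m, 6.72 ± 0.69) and fabp3.L (Xelaev18012061m, 5.91 ± 0.56), and the retinol binder rbp2.L (Xelaev18027897m, 6.61 ± 1.23) rose. The folate receptor folr4.L (Xelaev18023114m, 6.69 ± 0.61), the globin hbd.L (Xelaev18045080m, 6.65 ± 0.34), the cone opsin opn1lw.1 (Xelaev18003536m, 5.89 ± 0.52), the rod transducin gnat1.L (Xelaev18023829m, 5.24 ± 0.61) and the lens channel mip.L (Xelaev18013393m, 4.58 ± 0.53) rose too. Keratins krt.L (-5.80 ± 0.31) and krt18.S (Xelaev18016071m, -4.09 ± 0.33) fell, with adhfe1.S (-4.88 ± 0.47) and angptl7.L (Xelaev18035194m, -3.97 ± 0.87). So did the transporters slc5a1.2.L (Xelaev18007589m, -3.61 ± 0.39) and slc38a8.L (Xelaev18022485m, -3.58 ± 0.63), ido1.L (Xelaev18018656m, -3.50 ± 0.64), the collagen col8a1.L (Xelaev18011592m, -3.50 ± 0.84), szl.L (Xelaev18017689m, -3.48 ± 0.61) and hoxb9.S (-3.44 ± 0.44). Adjusted p ran from 1.41e-07 to 0.00461 in those that rose and 1.45e-07 to 0.0242 in those that fell. With the library, the 13 that rose had adjusted p from 0.141 to 0.664.

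Liver genes lay above the other genes without the library (21 higher, 2 lower, 11 not called; 26 higher and 2 lower adjusted over the list alone; median 2.55, camera adjusted p = 2.95e-36 and 0.1 with an estimated correlation). With it 0 rose (2 lower, 32 not called, also adjusted over the list alone; median 0.86, camera adjusted p = 0.00759, 0.133 after median-of-ratios scaling and 0.849 with an estimated correlation, alternatives from 2.95e-36 to 0.849). Lens genes lay above without it (9 higher, 4 not called, also adjusted over the list alone; camera adjusted p = 4.37e-16 and 0.165 with an estimated correlation) but not with it (0 of 13 called, also adjusted over the list alone; camera adjusted p = 0.0687). Retina genes did likewise (12 higher, 1 lower, 16 not called; 14 higher and 3 lower adjusted over the list alone; camera adjusted p = 2.76e-10 and 0.327), but not with it (3 lower, 26 not called; 4 lower adjusted over the list alone; camera adjusted p = 0.181). Hox genes lay below both with the library (29 lower, 43 not called; 50 lower adjusted over the list alone; camera adjusted p = 6.63e-17 and 0.746) and without it (14 lower, 58 not called; 29 lower adjusted over the list alone; camera adjusted p = 1.4e-10 and 0.314). Epidermis and keratin genes did too, with it (9 lower, 17 not called; 17 lower adjusted over the list alone; camera adjusted p = 1.98e-07 and 0.746) and without it (1 higher, 10 lower, 15 not called; 1 higher and 11 lower adjusted over the list alone; camera adjusted p = 3.08e-07 and 0.224). Skeletal muscle genes (8 lower, 30 not called; 17 lower adjusted over the list alone) lay below with the library (camera adjusted p = 6.95e-05 and 0.849 with an estimated correlation) but not without it (camera adjusted p = 0.845). Oocyte and egg maturation genes (0 of 29 called, also adjusted over the list alone) lay above with it (median 1.66, camera adjusted p = 6.36e-09 and 0.849 with an estimated correlation) but not without it (camera adjusted p = 0.735).

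limma called 131 models higher and 1062 lower (10.98% higher). Without the library labelled stage 40 Ueno the counts were 942 and 491 (65.7% higher). Among them were 65 of the 131 and 383 of the 1062 calls. Median-of-ratios scaling gave 281 and 500 (35.98%) and quantile normalization 585 and 988 (37.2%). The median of all genes was -0.26 in TPM and -0.09 after median-of-ratios scaling. In this contrast 1867 genes moved by over 1 log2 unit in opposite directions in the 2 clutches, against 105 or fewer in each other contrast. Leaving out stage 30 Taira, stage 30 Ueno, stage 40 Taira and the library labelled stage 40 Ueno in turn gave 3 and 44, 3 and 70, 5976 and 9389, 942 and 491 higher and lower. Of the named genes, 18, 17, 0 and 4 were then not called. Without any 1 library of stages 8 to 25 or egg Taira, 66 to 85 were higher and 519 to 718 lower.

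**Figure D3:**
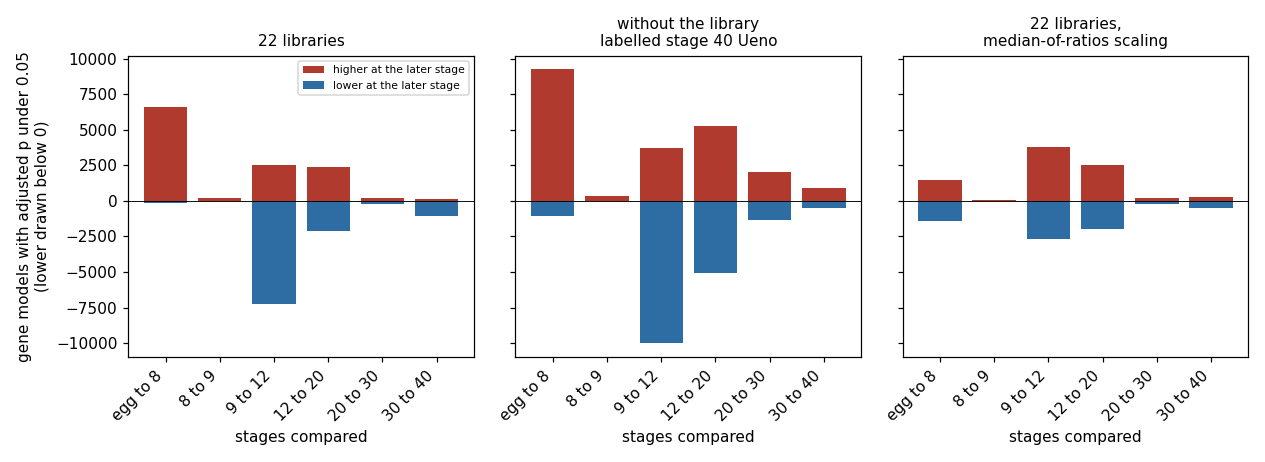
Gene models called higher or lower by limma (bars, number of models, adjusted p under 0.05) in the 6 stage contrasts, in panels for 22 libraries, for the fit without the library labelled stage 40 Ueno and for median-of-ratios scaling. From egg to stage 8 the bars read 6589 and 150, 9250 and 1045 and 1457 and 1436, and from stage 20 to stage 30 175 and 216, 2025 and 1325 and 207 and 247.

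Between the clutches, the methyltransferase comt.L (Xelaev18007704m, 2.85 ± 0.27) had the largest excess in Taira (log2 Taira minus Ueno). It was at 71.6 ± 61.0 TPM in Taira and 15.8 ± 22.3 in Ueno (SD over 11 stages). The ubiquitin-like modifier ufm1.S (Xelaev18016145m, 2.33 ± 0.27), nonmuscle myosin myh9.S (Xelaev18025550m, 2.02 ± 0.29) and the septin sept7-like.L (Xelaev18031285m, 1.99 ± 0.25) were higher in Taira at all 11 stages. So were the spindle gene spag5.L (Xelaev18011702m, 1.98 ± 0.25), the nucleolar genes dkc1-like.L (Xelaev18038552m, 1.98 ± 0.31) and gnl2.L (Xelaev18012510m, 1.93 ± 0.34), and the mRNA decay factor upf2.S (Xelaev18020924m, 1.88 ± 0.24). Higher in Ueno were the RNA-binding genes hnrnpa0.S (Xelaev18021532m, -1.73 ± 0.22) and hnrnpa0.1 (Xelaev18004598m, -1.43 ± 0.17), ptgfrn.S (Xelaev18014496m, -1.63 ± 0.24), josd2.L (Xelaev18023872m, -1.61 ± 0.37), hbox10.S (Xelaev18036595m, -1.53 ± 0.53) (-0.95 without the pair of stage 40), the glycogen regulator ppp1r3c.2.L (Xelaev18018779m, -1.52 ± 0.36), the mannosyl synthase subunit dpm1.L (Xelaev18043450m, -1.44 ± 0.14) and the repair factor tonsl.L (Xelaev18032513m, -1.37 ± 0.32), at 10 or 11 of the stages. Adjusted p ran from 0.00037 to 0.00139 in the 8 Taira genes and 0.00037 to 0.0387 in the 8 Ueno genes. With all 22 libraries and against a median of 0.38 in all genes, oocyte and egg maturation genes (median -0.41, 1 higher in Taira and 0 in Ueno, camera adjusted p = 8.55e-05) and ribosomal proteins (median -0.01, 2 and 0, 0.00011) lay lower. So did germ plasm (median 0.08, 3 and 0) and pluripotency genes (median 0.14, 4 and 2; camera adjusted p = 0.0401 each), whose medians were still above 0. Neuronal genes (median 0.76, 17 and 0) lay above the other genes (camera adjusted p = 0.0401). All 5 lists had an adjusted p of 0.946 with an estimated correlation. The pair of stage 40 holds the library labelled stage 40 Ueno, and without it the oocyte (median 0.24), germ plasm (0.36) and neuronal lists (0.46) were not called (camera adjusted p = 0.491, 0.843 and 0.213). Ribosomal (median -0.33, 5 higher in Taira and 27 in Ueno, camera adjusted p = 2.47e-20 and 0.0993 with an estimated correlation) and pluripotency genes (median 0.03, 6 and 4, 0.0436 and 0.939) still lay lower. Also lower then, and not called with all 22 libraries (camera adjusted p = 0.216 to 0.596), were the oxidative phosphorylation (median 0.08, 19 and 13, 0.00315), epidermis (0.04, 8 and 5, 0.0253), lens (-0.05, 0 and 0, 0.0254) and heart lists (-0.08, 6 and 2, 0.0436; 0.939 each with an estimated correlation). With median-of-ratios scaling as well, oxidative phosphorylation (-0.38, 3 and 35, 3.7e-07) and epidermis (-0.40, 3 and 13, 0.0121; 0.924 each with an estimated correlation) were called. Lens and heart were not (0.358 each), and with that scaling alone heart turned (0.796). That scaling alone also ended the calls of the germ plasm and pluripotency lists (camera adjusted p = 0.0668 and 0.071), and both medians then fell below 0 (-0.18 and -0.10). Over all alternatives, chosen after seeing the data except the estimated correlation, the lowest adjusted p was 0.0105 for oocyte and neuronal and 0.0668 for germ plasm genes, and for the other lists is given above. The highest was 0.946 to 0.987. limma called 9281 models higher in Taira and 905 in Ueno (91.1% in Taira, median 0.38). Median-of-ratios scaling gave 3267 and 2066 (61.3%, median 0.14) and quantile normalization 1786 and 2150 (45.4%). The excess depends on scaling. Without the pair of stage 40 the counts were 12657 and 1851, and without 1 other stage 6556 to 8802 and 654 to 898. P values rest on stages of 1 clutch per side, which cannot be separated from laboratory and date.

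The L to S ratio was compared in 6651 homeolog pairs. Pairs expressed almost wholly from L included the membrane protein serp2 (Xelaev18027711m and Xelaev18015768m, 7.66 ± 0.12), the GTPase rhoc (Xelaev18012343m and Xelaev18014808m, 7.63 ± 0.13), the channel vdac3 (Xelaev18018793m and Xelaev18020166m, 7.36 ± 0.18) and the rRNA processing gene utp23 (Xelaev18032305m and Xelaev18033958m, 6.84 ± 0.13), given as log2 of L over S. For nudt21 (Xelaev18022534m and Xelaev18024791m) and the chaperone dnaja4.1 (Xelaev18007338m and Xelaev18010300m) the S copy was listed at 0 throughout, with L at 211 and 159 TPM. On the S side were the splicing factor sf1 (Xelaev18022346m and Xelaev18024162m, -8.32 ± 0.25), the ribosomal protein rpl39 (Xelaev18038887m and Xelaev18042218m, -8.14 ± 0.26), the keratin krt5.1-like.2 (Xelaev18039959m and Xelaev18041035m, -7.26 ± 0.18), sh3bgrl3 (Xelaev18012114m and Xelaev18015056m, -6.51 ± 0.24) and the RNA-binding hnrnpul1 (Xelaev18039342m and Xelaev18042545m, -6.35 ± 0.16). The L copy of myeov2 (Xelaev18027877m and Xelaev18029921m) was listed at 0 with S at 115 TPM. Adjusted p was 3.12e-12 or lower in all 12. Other pairs changed sides with stage: the glutathione peroxidase gpx3 (Xelaev18016922m and Xelaev18020033m, -1.83 ± 0.10) went from 1.98 at stage 9 to -6.62 at stage 25. The nucleoside phosphorylase pnp (Xelaev18007331m and Xelaev18010299m, 0.39 ± 0.07) went from -1.96 in the egg to 4.43 at stage 12. The chloride channel gene clca3p-like (Xelaev18023366m and Xelaev18025422m, 2.00 ± 0.11), ficd (Xelaev18007453m and Xelaev18010387m, -1.01 ± 0.08), the thiolase acaa2 (Xelaev18008452m and Xelaev18011100m, -0.45 ± 0.08), btbd6 (Xelaev18039766m and Xelaev18041148m, -0.99 ± 0.10), rassf7 (Xelaev18022186m and Xelaev18024245m, 0.87 ± 0.09) and the phosphofructokinase pfkp (Xelaev18030710m and Xelaev18032852m, 1.86 ± 0.15) also did (adjusted p of the stage term from 8.37e-08 to 2.34e-06).

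L was called higher in 3327 pairs and S in 2280 (59.3% L), 1582 and 989 of them over 2-fold, with a median of 0.19. The ratio differed among stages in 5082 pairs (76.4%), and 757 of these changed sign by at least 1 log2 unit on each side. Over 2965 pairs expressed in all 22 libraries, the median ratio was 0.143 ± 0.0194 (SD, n = 4) in egg and stage 8 and 0.243 ± 0.0426 (n = 16) at stages 10.5 to 40. This filter was chosen after seeing the data (two-sided exact permutation within clutch, p = 0.00148, smallest possible 0.000494). The planned set of all pairs gave 0 and 0.155 ± 0.0843 (exact permutation p = 0.00148), with unexpressed pairs entered as 0. Without the library labelled stage 40 Ueno p was 0.000617 (exact permutation, smallest possible). P values rest on successive stages of 2 clutches, not on replicates. The authors' quantification divides reads of near-identical copies, so their ratios are uncertain.

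**Figure D4:**
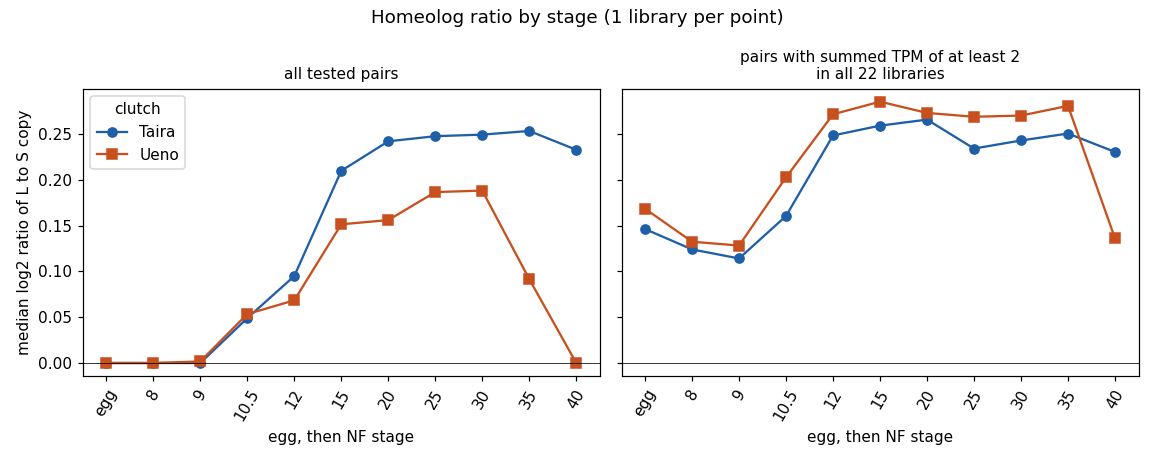
Median log2 ratio of L to S copies by stage (points, 1 library each, a line per clutch) for all tested pairs and for the pairs with a summed TPM of at least 2 in all 22 libraries. In the latter, egg and stage 8 average 0.143 and stages 10.5 to 40 average 0.243.

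In the oocyte libraries (n = 1 each, no test), values are log2 ratios of TPM + 1. From class 1-2 to 5-6, the DNA-binding hmgb3.S (Xelaev18042188m, 3.91), the nucleolar nolc1.L (Xelaev18034881m, 3.85), march7-like.S (Xelaev18047125m, 3.99) and arl4a.S (Xelaev18033007m, 3.78) were higher. So were ascc2.S (Xelaev18010356m, 3.77), the translation factor eif4g2.S (Xelaev18024574m, 3.65), syf2.L (Xelaev18030925m, 3.62) and sumo3.1 (Xelaev18000461m, 3.53). Lower were the avidin avd.2.L (Xelaev18044063m, -2.44), the respiratory genes ndufa13.1 (Xelaev18001739m, -2.29), ndufc1.S (Xelaev18009290m, -2.10) and ndufa11.S (Xelaev18009832m, -2.05), and gpx1.L (Xelaev18023802m, -1.99). So were the ribosomal protein genes rpl36.S (Xelaev18009635m, -2.25), rpl35.S (Xelaev18041822m, -2.16) and rpl23.S (Xelaev18045948m, -1.93). From class 5-6 to egg Ueno, ncoa6.1 (Xelaev18004673m, 5.74), the cap binder ncbp1.S (Xelaev18009967m, 5.51), cpeb2-like.L (Xelaev18005140m, 5.44), plekha1.L (Xelaev18034524m, 5.39), tnrc6a-like.L (Xelaev18045467m, 5.38), ets2.S (Xelaev18014341m, 5.27) and the cohesin rad21.S (Xelaev18033959m, 5.21) were higher. For g0s2.S (Xelaev18014639m, 5.81) egg Taira was listed at 0 where egg Ueno had 60.2 TPM. The retinol binder rbp2.L (-8.06), the folate receptor folr1.L (Xelaev18013914m, -7.65), naa10.S (Xelaev18041887m, -7.61) and the steroid enzyme hsd17b12.S (Xelaev18024537m, -7.45) were lower. So were hs3st1.L (Xelaev18005131m, -7.26), the malate dehydrogenase mdh1.S (Xelaev18028486m, -7.22), polr1c.L (Xelaev18026389m, -7.15) and gtpbp4-like.L (Xelaev18030704m, -7.07). With egg Taira in place of egg Ueno the falls of these 8 were smaller, at -3.22, -4.03, -2.77, -4.75, -2.78, -2.61, -3.85 and -3.68 in the order named. Ribosomal protein genes had a median of -1.15 from class 1-2 to 5-6 and -1.71 from 5-6 to egg, with 31 and 43 of 53 members over 2-fold lower (percentile 0 at both steps among 10000 random lists of the same size and mean expression, as a description of these libraries only). Oxidative phosphorylation genes had medians of -0.41 and -2.70, with 25 and 73 of 87 over 2-fold lower (percentile 0). Germ plasm and cell cycle genes had medians of 1.38 (percentile 99.8) and 0.90 (percentile 100) from class 1-2 to 5-6, against 0.73 in all models. Among 19295 models, 6978 were over 2-fold higher and 524 lower from class 1-2 to 5-6, and 3522 and 8358 from 5-6 to egg Ueno (median -0.66). With egg Taira in place of egg Ueno the latter were 4306 and 6555 (median -0.32).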

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

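The tests of an egg under a wrong label, of a mixture, of a swap, of TPM scaling between egg and stage 8 and between the clutches, and of random splits were chosen only after the result was seen, as were the bound of 1 log2 unit and the second-series genes below. The other tests were written before. The globin hba-l5.Sp changed from stage 30 to stage 40 by 3.40 log2 units in Taira and by -2.56 in Ueno, the latter drawn from the library labelled stage 40 Ueno, and this difference was not tested. Of the second Ueno series, stage 10 entered no fit and stage 35 only an alternative. Stage 10 had 343 TPM of t.L, 51.8 of gsc.L, 121 of sox2.S and 99.7 of myod1.S. Stage 35 had 320.0 TPM of actc1.L and 77.5 of hba-l5.Sp.

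The library labelled stage 40 Ueno has the ranks of an egg library. An egg library, or a library close to it, under the stage 40 label would fit: genes with at least 50 TPM in stage 40 Taira and under 1 in both eggs were at a median of 0% of the Taira level in it. Tadpole RNA mixed with egg RNA would leave part of that level, but the upper quartile was 0.0779%. A swap with egg Ueno would make that library a tadpole, but its correlation with stage 40 Taira was 0.483. Which RNA the library held could be settled only by the submitters, and the contrast from stage 30 to stage 40 likely mixes a tadpole with an egg-like library (131 higher and 1062 lower with it, 942 and 491 without it).

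Most genes lower in egg than in class 5-6 oocytes were higher again at stage 8 (89.7% in Taira and 67.9% after median-of-ratios scaling), but medians of ribosomal proteins went on down from egg to stage 8 (-0.54 in Taira and -0.48 in Ueno) and those of oxidative phosphorylation genes were -0.20 and 0.40. In Taira, which was not used to choose them, genes that fell from oocyte to egg in Ueno changed by 1.90 log2 units more from egg to stage 8 than genes that rose (1.93 after that scaling), which argues against a property of the egg Ueno library alone. Their median was still 1.22 without the most abundant models, which argues against TPM scaling set by a few of them, but TPM scaling as such cannot be told apart from part of the rise, since the median was 0.41 after median-of-ratios scaling and all models moved from 0.69 to -0.10. A change in poly(A) tails without new RNA cannot be told apart from new RNA by the design: 6.77% of the genes that fell were over 2-fold above the oocyte at stage 8. Polyadenylation of stored RNA may contribute, since all libraries selected polyA RNA, and no biological explanation was tested.

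Most called genes of the clutch comparison were higher in Taira (91.1%). TPM scaling cannot be told apart from a difference of the clutches, since 61.3% were higher in Taira after median-of-ratios scaling and 45.4% after quantile normalization. Fewer low genes seen in the Ueno libraries cannot be told apart either, as the median of genes with a mean TPM of at least 50 was 0.141 (594 higher in Taira and 463 in Ueno) and -0.30 after median-of-ratios scaling. Of 100 splits with clutch swapped within stages, 1 (the real split) gave 10186 called genes, and the highest other 0. Swaps turn differences shared by stages into spread, so chance was not tested. The cause remains open.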

How the results depend on the processing

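The fits without a library of a stage that the contrast does not use, those without the library labelled stage 40 Ueno with other settings or without both late Ueno libraries, list tests with libraries left out or scaled, and the clutch comparison with both are the tests chosen only after the result was seen, and the other tests were planned. With n = 2 per stage each contrast rests on the spread pooled over 11 stages, and where 1 library of a stage is left out the lone sample is assumed to vary like the other groups. Below, "higher and lower" counts are for the later stage, and causes other than those given were not tested.

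The ranges of counts that follow are over the 2 libraries of each compared stage, stage 35 Ueno and the library labelled stage 40 Ueno, each left out in turn. From egg to stage 8, 3137 to 9250 were higher and 37 to 1045 lower, from 8 to 9 54 to 319 and 0 to 7, from 9 to 12 1570 to 3725 and 4071 to 10014, and from 12 to 20 607 to 5277 and 518 to 5086. From 20 to 30 there were 6 to 2025 and 25 to 1325, and from 30 to 40 3 to 5976 and 44 to 9389. Without stage 40 Taira some limits were passed (2037 and 1350 from 20 to 30). Up to stage 30, leaving out either stage 40 library takes the pair's difference out of the pooled spread. With each of the 22 libraries left out, genes that differ among the 11 stages were 21454 to 25796, and with each stage left out clutch counts were 6556 to 12657 in Taira and 654 to 1851 in Ueno. Pairs whose L to S ratio differs among stages were 4536 to 5752, with L higher in 3244 to 3435 and S in 2227 to 2363, and the difference of early and late medians was -0.165 to -0.149.

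Without a replicate block, counts were 3646 and 67 from egg to stage 8, 1091 and 924 from 12 to 20, 53 and 73 from 20 to 30 and 32 and 193 from 30 to 40. Median-of-ratios scaling gave 1457 and 1436 from egg to stage 8, 77 higher from 8 to 9, 2680 lower from 9 to 12, 281 and 500 from 30 to 40, and 3267 and 2066 for the clutches. Quantile normalization gave 1286 and 549 from egg to stage 8, 62 and 1 from 8 to 9, 3457 lower from 9 to 12, 476 and 447 from 20 to 30, 585 higher from 30 to 40, and 1786 and 2150 for the clutches. A pseudocount of 0.1 gave 67 and 90 from 20 to 30 and 76 and 416 from 30 to 40. A pseudocount of 5 gave 1 lower from 8 to 9 and 3841 genes over 2-fold higher from oocyte class 1-2 to 5-6 (6978 with a pseudocount of 1). Without a filter there were 4 lower from 8 to 9 and 81 and 601 from 30 to 40. A filter at TPM of at least 5 left 6 of 11 Taira libraries closest to their own stage (7 in the main comparison). The second Ueno series added gave 268 higher from 20 to 30 and 243 and 1949 from 30 to 40.

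Without both late Ueno libraries, 1165 were lower from egg to stage 8, and counts were 315 and 1 from 8 to 9, 5507 and 5323 from 12 to 20, 2512 and 1575 from 20 to 30 and 1258 and 619 from 30 to 40. Without the library labelled stage 40 Ueno and with median-of-ratios scaling, they were 3788 and 5831 from egg to stage 8, 6470 higher from 9 to 12, 6192 and 5200 from 12 to 20, 2838 and 1652 from 20 to 30 and 1656 and 410 from 30 to 40. With quantile normalization in its place they were 3601 and 3589 from egg to stage 8, 2 lower from 8 to 9, 5461 higher from 9 to 12, 5422 and 6092 from 12 to 20, 2910 and 2259 from 20 to 30 and 1665 higher from 30 to 40. With no replicate block they were 359 lower from egg to stage 8, 1127 and 437 from 20 to 30 and 805 and 184 from 30 to 40. The clutch comparison without the pair of stage 40 and with median-of-ratios scaling gave 4482 in Ueno.

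Across the alternatives of the 180 list tests, 34 results were in the other direction, some of the same list and contrast. After median-of-ratios scaling 14 were, with adjusted p from limma's camera from egg to stage 8 of 0.133 for early zygotic, 0.351 for pluripotency, 0.856 for brain, 0.978 for hox, 0.658 for muscle, 0.572 for heart, 0.338 for lens, 0.889 for retina, 0.678 for notochord and 0.5 for mRNA clearance genes. From 8 to 9 these were 0.971 for liver and 0.852 for pancreas, and from 9 to 12 0.971 for blood and 0.792 for pancreas. The main tests of these had adjusted p from 0.000373 to 0.953, and all their alternatives 0.000454 to 0.979. Without a replicate block the pluripotency list turned from egg to stage 8 (0.942; alternatives 0.351 to 0.979). Without the library labelled stage 40 Ueno 19 turned: from egg to stage 8 pluripotency (0.949) and thyroid (0.815), from 8 to 9 endothelium (0.76) and liver (0.478), from 12 to 20 lens (0.977), and from 20 to 30 cement gland (0.897). From 30 to 40 these were germ plasm (0.028), neurons (0.0423), muscle (0.845), heart (0.00272), blood (0.0135), gut (0.472), pronephros (0.815), notochord (0.177), ribosomal (6.42e-09), oxidative phosphorylation (5.62e-13), cell cycle (0.0102), mRNA clearance (0.0475) and immune genes (0.209). The main tests of these 19 had 2.44e-05 to 0.955, and their alternatives 5.62e-13 to 0.987. With an estimated correlation 87 of the 89 called list tests were lost. Of the clutch lists, 7 turned without the pair of stage 40: neural crest, hox, gut and mRNA clearance (0.843 each), muscle (0.34), notochord (0.789) and cell cycle (0.491). With median-of-ratios scaling as well these had 0.906, 0.859, 0.976, 0.976, 0.712, 0.859 and 0.976 in the same order. With that scaling alone, heart (0.796), blood (0.596) and thyroid lists (0.993) turned. The main tests of these 10 had 0.216 to 0.912, and all their alternatives 0.0436 to 0.997.

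Across settings, 301 counts or medians stayed similar (as 9250 for 6589 higher from egg to stage 8) and 120 moved. Among list results 547 kept a call or no call, 25 grew stronger and 114 weaker. Named stage genes kept 1723 calls and lost 237, 4 without the library labelled stage 40 Ueno and 149 with 1 other left out. Of the clutch list results 79 stayed, 10 grew stronger, 14 weaker and 17 turned. Among clutch genes 296 stayed and 8 grew weaker. All 324 results of the 12 pairs with an L or S excess stayed, but pairs changing sides were not included. No named gene changed direction.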

Other observations

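In this part the 2 fits from stage 20 to stage 30 without a late Ueno library were chosen after the result was seen. Transthyretin, a liver plasma protein, was abundant in stage 40 Taira from both copies (ttr.L 4665 and ttr.S 5489 TPM). The library labelled stage 40 Ueno had 0 of both. The retinol binder rbp2.L was among the genes that fell most from class 5-6 oocytes to egg Ueno (-8.06, -3.22 to egg Taira) and rose by 6.61 ± 1.23 from stage 30 to stage 40 Taira. In the eggs myod1.L was at 53.5 and 186 TPM and its homeolog myod1.S at 0 and 0.0900.

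Stage 35 Ueno had 53.6% of models at 0, and its lowest value above 0 was 0.0800 TPM. Without it 169 were higher and 196 lower from stage 20 to stage 30 (175 and 216 with it; 2025 and 1325 without the library labelled stage 40 Ueno). Oocyte class 5-6 held 37.8 TPM of gsc.S, where stage 10.5 had 87.5 and 48.2 (Taira and Ueno).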
